A study of Homo sapiens with 4 samples.

How the data were processed

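Circular RNAs were counted in total RNA of WI-38 cells, a line of diploid fibroblasts from human fetal lung that stops dividing after a limited number of population doublings. The 4 libraries form 2 groups of 2, proliferating cells at population doubling level (PDL) 20 and 23 and senescent cells at PDL 50 and 54, and no sample received a treatment. Libraries are named here by their PDL. The labels number no replicates across groups, so no library was paired with another. Nothing in the labels says whether the 2 libraries of a group came from separate cultures. The p-values therefore measure at most the spread between these samples, which may be technical.

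Per the labels' protocols, ribosomal RNA was removed, the remaining RNA was turned into cDNA and amplified with a NuGEN Ovation kit, the cDNA was fragmented by sonication, adaptors were ligated, fragments of 300 to 350 bp were selected and 17 cycles of PCR followed. Amplification comes before and after fragmentation and no molecular identifier is mentioned, so reads are not independent molecules. All intervals and floors given here cover counting error only. Per the submitters' processing notes, cutadapt and TopHat were used with the human genome build hg19. Their versions, and the program that called the circles, are not given in the sources used here.

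The deposited files hold, per library, 1 line per circle with its chromosome, start, end, strand, host gene, transcript, exon or intron number, exon sizes and an unnormalised read count. That count is the number of reads that cross the back-splice, the junction at which a downstream end is joined to an upstream start. The authors' files list only circles with at least 1 read, so a circle missing from a file was counted as 0 in that library. The files type each entry as exonic (from a downstream exon end to an upstream exon start) or intronic (within 1 intron). Coordinates are printed 1-based on hg19 as the files give them, and exon numbers refer to the transcript the files name. No reference sequence of another build was used for positions. Host genes are those named in the files; where genes overlap, the named host is uncertain.

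Each library's size was its total of back-splice reads, 4148 at PDL 20, 3313 at PDL 23, 3114 at PDL 50 and 7475 at PDL 54. Levels are given as reads per 1000 back-splice reads of the library, as mean ± SD over 2 libraries. A floor of 3 reads in a library corresponds to 0.723 per 1000 at PDL 20, 0.906 at PDL 23, 0.963 at PDL 50 and 0.401 at PDL 54. Where a whole group had no read, the bound on the fold is the other group's mean per 1000 divided by 3 reads over the summed total of the group without reads, 0.402 per 1000 for proliferating and 0.283 for senescent libraries. Where it had 1 read or more, the ratio of the summed reads per total is given with its exact 95% counting interval. The bound on the fold takes the other group's mean as exact, so it is not a confidence limit.

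Circles with a mean of at least 3 reads over the 4 libraries, after scaling to the median library total, were tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3, TMM factors), with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 110 circles, and circPVT1 was tested whatever its level, which makes 111. The same test was run on the reads summed per host gene, 193 genes after the same filter. Standard errors of log2 fold changes were derived from the same fits. The 9 lists of host genes, fixed from general knowledge, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 3 members passed the filter, which held for 5 lists. Shares of a library have exact Clopper-Pearson 95% intervals. Single values per library were compared by an exact two-sided permutation test, which with 2 against 2 cannot give a p below 0.333. For equal depth, expected numbers of circles were computed by exact hypergeometric thinning to 3114 reads.

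The tests were tested on simulated counts. With 20 of 110 circles changed and the dispersion of these libraries, the circle test recovered 0% of 4-fold and 4% of 16-fold changes; at a dispersion of 0.1 it recovered 53.5% and 98.5%. The host gene test recovered 1.5% of 4-fold and 15% of 16-fold changes among 193 genes at the observed dispersion. camera called 19 of 20 simulated lists whose 10 members were shifted 4-fold. Those calls were at an unadjusted p under 0.05, with independent members all shifted the same way. Most lists tested here had fewer members and were judged on an adjusted p, so the simulation does not give their power.

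Before the data were examined, the groups, tests, filters, lists, alternatives and the rule for named items were fixed. The rule takes circPVT1, identified as the single-exon circle of PVT1 with an exon of 410 nt; up to 12 circles per direction, filled by smallest unadjusted p among circles whose groups do not overlap where none pass; the 10 circles with the highest mean scaled count; up to 3 host genes per list by smallest p; and the 5 host genes per direction with the smallest p. Alternatives were other size factors (RLE or totals only), other filters (1.5, 6, none, a raw total of 10, or detection in all 4 libraries), PDL as a numeric covariate, DESeq2 1.42.0, an estimated inter-gene correlation and leaving out each library. Added after seeing the data were exonic circles only, unfiltered list tests with an estimated correlation, with exonic circles or with no library at PDL 20, list shares with each circle counted once, the matrix list without THBS1, and the bounds with 1 library left out. All values were computed in R or in Python 3.11.15 with scipy 1.17.1.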

Results

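Back-splice reads of circular RNAs, closed loops made when a downstream splice site joins an upstream one, were counted in 2 libraries of proliferating and 2 of senescent WI-38 fibroblasts. The comparison asks which circular RNAs differ in level between dividing cells and cells at the end of their replicative lifespan, and the series title singles out circPVT1. The files list 964 circles from 4148 reads at PDL 20, 2093 from 3313 reads at PDL 23, 1361 from 3114 reads at PDL 50 and 3466 from 7475 reads at PDL 54. Together they hold 6912 circles from 3005 host genes. Of these circles 6220 (90.0%) were listed in 1 library, 474 in 2, 156 in 3 and 62 in all 4. Exonic circles carried 55.0% and 57.6% of the reads in the proliferating libraries and 52.9% and 67.9% in the senescent ones.

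circPVT1, the circle of exon 2 of PVT1, a long non-coding RNA gene on chromosome 8 (128902835 to 128903244, plus strand, 410 nt), had 1 read at PDL 23 and 0 reads in the other 3 libraries. Both groups lay at or under the floor of 3 reads, so no fold is given, and a difference was not detectable at this depth (edgeR adjusted p = 0.913). Other circles had their reads almost wholly in one group. The circle of exons 2 to 7 of ADAMTS6, a secreted metalloprotease gene, had 54 and 12 reads in the proliferating libraries and 0 and 4 in the senescent ones. The circle of exons 2 to 4 of EPB41L2, which encodes a membrane-skeleton protein, had 0 and 3 reads against 26 and 29. No circle passed the test: of 111 circles, 0 had an edgeR adjusted p under 0.05 and the smallest adjusted p was 0.476. At an unadjusted p under 0.05 there were 8 circles by edgeR, 4 higher and 4 lower in senescent cells, and 17 by DESeq2, of which 0 passed adjustment.

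Among circles with more reads in both senescent libraries, none of which passed, EPB41L2 (chromosome 6, 131247745 to 131277639) had a log2 fold change of 3.54 ± 1.74 (SE, n = 2 per group). Its pooled reads were 12.9 times higher in senescent libraries, with a counting interval of 4.20 to 64.6, and 5.74 times without PDL 20. FAM73A exons 2 to 8 (chromosome 1, 78248923 to 78309092) had 0 and 0 proliferating reads against 9 and 15 senescent ones, at least 6.09-fold higher. EIF4G3, a translation initiation factor gene, gave a circle of exons 8 to 12 (chromosome 1, 21220010 to 21268823) with 0 and 0 against 5 and 17 reads, at least 4.82-fold higher. Without PDL 20 these bounds were 2.70 for FAM73A and 2.14 for EIF4G3, since fewer reads then back the 0. The circle of FNDC3B exons 2 to 6 had 3 and 17 senescent reads and that of MAN1A2, a Golgi mannosidase gene, exons 2 to 8 had 12 and 3, both with 0 in proliferating cells. Single libraries held most reads of 2 further circles with 0 proliferating reads, GPATCH2L exons 3 to 10 with 19 at PDL 50 and 4 at PDL 54, and ADAMTS19 exons 17 to 21 with 1 at PDL 50 and 40 at PDL 54. BMPR2, a receptor gene for bone morphogenetic proteins, gave a circle of exons 2 to 7 with 0 and 1 against 13 and 8 reads. THBS1, which encodes the secreted matrix glycoprotein thrombospondin-1, supplied the remaining 4 of the 12, a circle of exons 1 to 2 with 0 and 0 against 11 and 1 reads and 3 intronic entries in intron 7. The most read of these intronic entries (chromosome 15, 39877765 to 39878250) had 0 and 1 against 21 and 8 reads.

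Among circles with a lower level per 1000 reads in both senescent libraries, which did not pass either, ADAMTS6 (chromosome 5, 64747302 to 64769779, minus strand, 1352 nt) had the smallest p. Its log2 fold change was -4.37 ± 1.61 (SE, n = 2 per group; edgeR adjusted p = 0.476), from 8.32 ± 6.64 per 1000 reads (SD) in proliferating to 0.268 ± 0.378 in senescent libraries. The circle of exon 2 of HAS2 (chromosome 8, 122640954 to 122641580), the gene of a hyaluronan synthase, had 18 and 2 proliferating reads and 0 senescent ones, at least 8.72-fold lower. USP3, a histone deubiquitinase gene, gave a circle of exons 2 to 10 with 15 and 3 against 0 and 0 reads, at least 7.98-fold lower. Without PDL 20, which held most of these reads, the bounds were 2.13 for HAS2 and 3.20 for USP3, and without PDL 54 they were 2.57 and 2.35. DENND4C exons 3 to 10 (27 and 1 reads) and VRK1 exons 2 to 11 (14 and 1 reads), the latter from a nuclear kinase gene, also had 0 senescent reads, and nearly all their reads came from PDL 20. ZMYM2 exons 13 to 21 had 9 and 11 against 0 and 3 reads. NIPBL exons 2 to 9, from the gene of the cohesin loader, had 17 and 4 against 2 and 1. The other 5 circles were lower per 1000 reads but not always in reads, since PDL 54 has the most reads in total. They ran from FMN1 with 21 and 10 against 1 and 16 reads to SP3 with 8 and 5 against 2 and 7. They included GLIS3, ZBTB44 and 1 further THBS1 intronic entry, with 6 and 6 against 1 and 3 reads. That entry (39877765 to 39878219) starts in intron 7 where the 3 higher THBS1 entries start, and the nearest of those ends at 39878234. Nearby ends of 1 intron thus stood in opposite lists. Of the 110 circles that passed the filter, 28 (25.5%) were higher in both senescent libraries than in both proliferating ones and 17 (15.5%) lower, where chance gives 16.7% per direction for libraries that detect circles alike. Of the 110 circles, 72 had a read at PDL 20, against 90 at PDL 23, 89 at PDL 50 and 101 at PDL 54.

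The most abundant circles were listed in both groups. The circle of ANKRD12 exons 2 to 7 (chromosome 18, 9182380 to 9221997) had 13.3 ± 2.63 reads per 1000 in proliferating and 20.2 ± 3.18 in senescent libraries (SD, n = 2 each), a log2 fold change of 0.66 with a 95% interval of -0.31 to 1.62. HIPK3 exon 2 (chromosome 11, 33307959 to 33309057), from a protein kinase gene, had 11.9 ± 4.93 and 15.1 ± 0.944, with an interval of -0.69 to 1.53. SLC8A1 exon 2 (chromosome 2, 40655613 to 40657444), from the gene of a sodium-calcium exchanger, had 9.83 ± 1.10 and 12.5 ± 0.475, with an interval of -0.87 to 1.59. SPECC1 exon 4 had 16.1 ± 11.7 and 11.9 ± 1.74, TJP1 exons 3 to 8, from the gene of the junction protein ZO-1, had 10.2 ± 5.22 and 14.8 ± 8.21, BPTF exons 23 to 29, from a chromatin remodeller gene, had 6.09 ± 2.64 and 9.49 ± 3.42, and HIPK2 exon 2 had 6.33 ± 2.14 and 4.86 ± 0.510. The sign of the differences in SPECC1, TJP1, BPTF, HIPK2 and LPAR1 depended on the library or filter used. A longer TJP1 circle of exons 2 to 8 (0 and 19 against 31 and 36 reads) and the circle of LPAR1 exons 2 to 4 (0 and 25 against 4 and 59) were missing at PDL 20 and listed in the other 3 libraries. The ADAMTS6 circle was the remaining member of the 10, which together took 8.88% ± 1.29 of reads in proliferating and 10.1% ± 1.55 in senescent libraries (exact permutation p = 0.667, n = 2 each). None of the 10 passed the test.

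**Figure D1:**
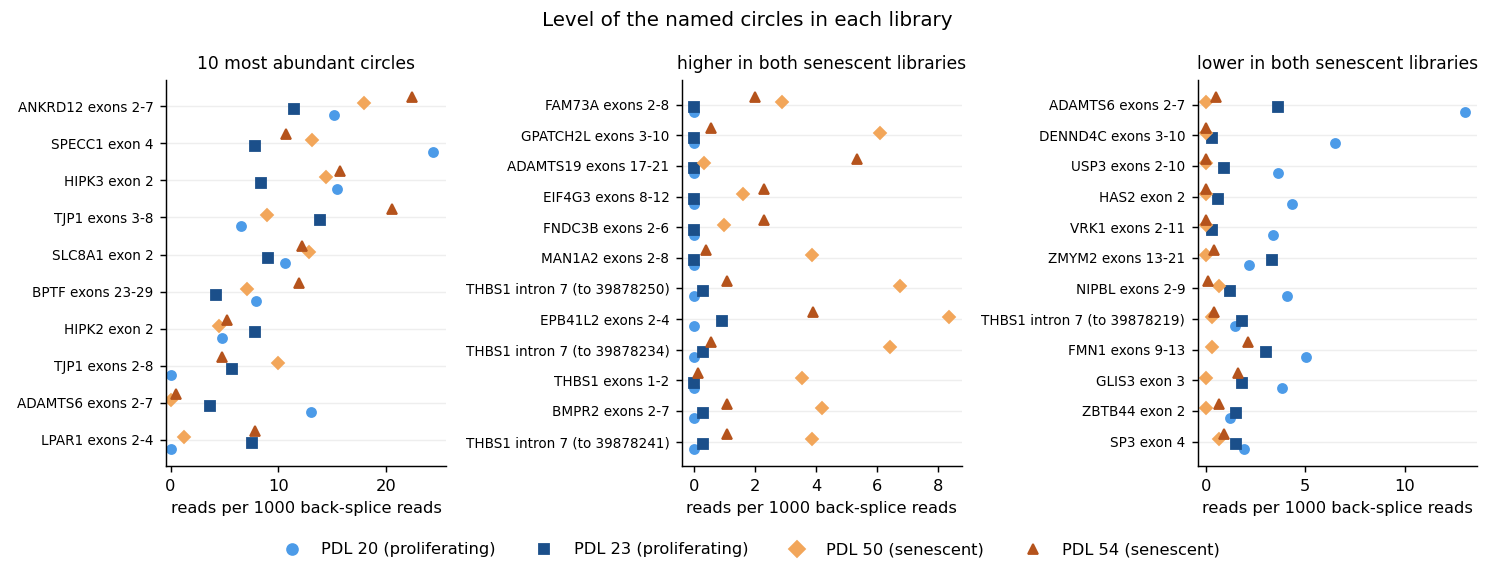
Reads per 1000 back-splice reads of the named circles in each of the 4 libraries, 1 point per library, for the 10 most abundant circles and for 12 circles each with a higher or lower level in both senescent libraries. ADAMTS6 lies at 13.0 per 1000 at PDL 20 and 3.62 at PDL 23 against 0 and 0.535 in the senescent libraries, and none of the differences passed the test.

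Reads summed over all circles of a host gene put BIRC5 and ADAMTS6 among the lower genes and ADAMTS19 and FMN2 among the higher ones, and none passed. BIRC5, which encodes the mitotic protein survivin, had 44 and 8 reads in proliferating and 0 and 3 in senescent libraries. All of these were on intronic entries in intron 2, with no exonic circle. The log2 fold change of BIRC5 was -4.09 ± 1.52 (SE, n = 2 per group, edgeR adjusted p = 0.483). With single libraries left out it ran from -3.17 without PDL 20 to -7.39 without PDL 54. ADAMTS6 had 60 and 18 against 0 and 8 reads. HAS2 (18 and 2), DENND4A (27 and 1 against 0 and 1) and WDR60 (33 and 0 against 0 and 0) completed the 5 lower genes with the smallest p, and the reads of WDR60 came from PDL 20 alone. On the higher side, ADAMTS19 (1 and 46 senescent reads), LRCH3 (4 and 16), the actin nucleator gene FMN2 (8 and 7) and the proteasome activator gene PSME4 (8 and 5) had 0 reads in both proliferating libraries, and CASC4 had 0 and 1 against 7 and 18. Some circles named above lost their order on summing: the groups overlapped for MAN1A2 (22 and 8 against 19 and 35 reads), GPATCH2L (5 and 0 against 19 and 6), FNDC3B (0 and 18 against 15 and 82) and DENND4C (27 and 1 against 0 and 5), and the log2 fold change of EPB41L2 was 1.43 ± 1.08. Of 193 host genes 0 passed (smallest edgeR adjusted p 0.281), with 18 at an unadjusted p under 0.05 by edgeR (8 higher, 10 lower) and 11 by DESeq2, of which 0 passed. Without the library at PDL 23, 8 host genes passed as lower in senescent cells, BIRC5, HAS2, DENND4A, WDR60, AIDA, CAPRIN1, IGF2R and RPL4, where the lone proliferating library was assumed to vary like the senescent pair.

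Circles of cell division and DNA replication genes took a smaller share of reads in both senescent libraries. The share was 1.30% at PDL 20 (95% interval 0.979 to 1.70) and 0.755% at PDL 23 (0.489 to 1.11), against 0.0642% at PDL 50 (0.00778 to 0.232) and 0.120% at PDL 54 (0.0551 to 0.228). Of the 78 listed genes 22 had any circle: 12 in proliferating libraries alone, 9 in both groups and KIF23, a kinesin gene of cell cleavage, with 1 read in senescent cells alone. CCNB1, which encodes cyclin B1, had 12 reads and WDHD1, a replication factor gene, had 9, all at PDL 20. CKAP5, a spindle microtubule gene, had 5 and 1 reads against 0 and 1, and MCM3, a subunit of the replicative helicase, had 0 and 4 against 0 and 2. In total 79 reads lay in proliferating and 11 in senescent libraries. The exact permutation test of the shares gave the smallest p that 2 against 2 allows, 0.333. No member had enough reads to pass the filter. With a filter of 1.5, 4 members were tested and the list did not pass camera (adjusted p = 0.138). With no filter camera called the list lower over 22 members (adjusted p = 1.36e-05) at the preset correlation, and did not with an estimated correlation (p = 0.0341, adjusted p = 0.273). The estimate was -0.0388, under the preset 0.01, so correlation between members does not account for the larger p. At a preset correlation camera takes the number of genes as its sample size, and with an estimated one the number of libraries. The p at the preset therefore does not measure the spread between libraries. Without the library at PDL 20, 15 members remained and the adjusted p was 0.00125 at the preset and 0.789 with an estimated correlation, with the lone proliferating library assumed to vary like the senescent pair.

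The share of the extracellular matrix list was high at PDL 50, where THBS1 held most of it, and its other genes did not all go one way. It took 8.32% and 8.12% of reads in the proliferating libraries and 19.3% and 5.54% in the senescent ones, and THBS1 alone took 3.88%, 5.28%, 17.4% and 4.05% in the same order. THBS1 had 161 and 175 against 541 and 303 reads, a log2 fold change of 1.42 ± 0.67 (SE, n = 2 per group; edgeR adjusted p = 0.484). Without PDL 50 the THBS1 value was 0.27. The other genes of the list together took 4.44% and 2.84% against 1.93% and 1.48%, though the metalloprotease gene ADAMTS12, chosen after its values were seen, had 1 and 4 against 7 and 13 reads. The list's exonic circles had the same order, with 3.03% and 2.41% against 2.19% and 0.906% of exonic reads. COL6A3, a collagen VI chain gene, had 22 and 8 against 1 and 6 reads. camera gave the list as lower without a call (adjusted p = 0.446), and so it did with THBS1 left out (unadjusted p = 0.180). Of the 9 tested members, 4 were higher and 5 lower, and 0 passed over all genes or adjusted over the list alone (smallest 0.0944 for ADAMTS6).

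Actin cytoskeleton and focal adhesion genes took 1.98% and 1.93% of reads in proliferating and 2.86% and 2.64% in senescent libraries. Of 8 tested members 6 were higher, among them FMN2, VCL, the gene of vinculin, with 0 and 2 against 6 and 10 reads, and PTK2, the gene of focal adhesion kinase, with 0 and 20 against 27 and 49. The list did not pass camera (adjusted p = 0.261), and 0 members passed adjusted over the list alone (smallest 0.180). Genes of RNA-binding proteins in splicing or circle formation took 1.33% and 1.60% of all reads against 0.674% and 1.02%, but the groups overlapped for exonic reads, with 0.877% and 2.20% against 0.789% and 1.08%. With 2 tested members the list was too small for camera, and with no filter it did not pass (adjusted p = 0.262). The tested members RBM39 and PTBP3 had log2 fold changes of -0.60 ± 1.38 and -0.37 ± 1.39 (SE), whose sign turned when a library was left out. Chromatin regulators, such as ASH1L with 1 and 6 against 8 and 20 reads and ARID1A with 0 and 5 against 7 and 12, had 5 of 8 tested members higher (camera adjusted p = 0.446). The well-described circular RNA hosts had 13 of 20 higher (camera adjusted p = 0.446), and their share lay between 9.09% and 11.4% in the 4 libraries. TGF-beta and SMAD genes had 2 of 4 higher, with ZEB1 at 6 and 7 against 0 and 2 reads and BMPR2 at 13 and 9 against 16 and 57 (camera adjusted p = 0.654). Of the senescence and p53 list only HMGA1 (5 and 7 against 0 and 8 reads) and the DNA damage kinase gene ATM (2 and 5 against 8 and 0) had enough reads to be tested, too few for camera, and the list took 0.289% and 0.573% of reads against 0.417% and 0.268%. In these 5 lists 0 genes passed over all genes or adjusted over the list alone. Markers of epithelial, endothelial, leukocyte and smooth muscle cells gave 3 reads in all, 2 of ACTG2 and 1 of KRT8, all at PDL 23.

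**Figure D2:**
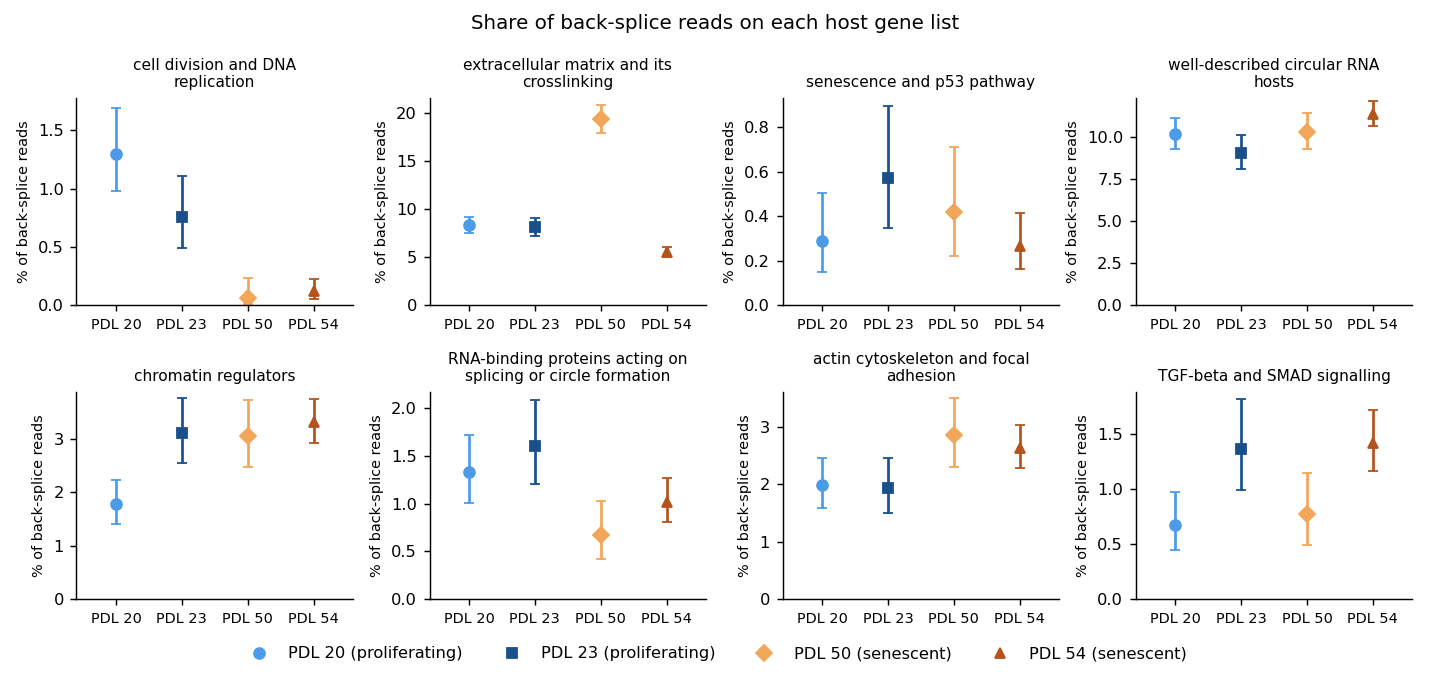
Percent of each library's back-splice reads on 8 host gene lists, 1 point per library (proliferating at PDL 20 and 23, senescent at PDL 50 and 54), with bars for exact 95% counting intervals. The cell division list lies at 1.30% and 0.755% against 0.0642% and 0.120%, and the extracellular matrix list stands apart at PDL 50 with 19.3%.

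The number of circles at equal depth and the share resting on a single read differed more between the 2 proliferating libraries than between the group means. At PDL 20 a circle had 4.30 reads on average and 25.5% of circles rested on a single read, whereas the values were 1.58 reads and 76.7% at PDL 23, 2.29 and 56.9% at PDL 50 and 2.16 and 67.0% at PDL 54. Thinned to 3114 reads, the libraries held 891 circles at PDL 20, 1995 at PDL 23, 1361 at PDL 50 and 1848 at PDL 54, so the groups overlapped (exact permutation p = 1, n = 2 each), and the order turned with the library left out, with a log2 ratio of senescent over proliferating of -0.31 without PDL 20 and 0.85 without PDL 23. Single-exon circles and intronic entries took 54.4% ± 2.90 of reads in proliferating and 50.2% ± 9.43 in senescent libraries (SD, n = 2 each, exact permutation p = 1). The read-weighted geometric mean length was 494 and 509 nt in proliferating and 523 and 586 nt in senescent libraries. Among exonic circles alone the order turned, with 882 and 808 nt against 799 and 790 nt. Both length comparisons gave an exact permutation p of 0.333, the smallest possible. Circles such as those of HIPK3, SLC8A1 and ANKRD12, which start at exon 2, held 38.8% ± 0.493 of exonic reads in proliferating and 40.4% ± 2.81 in senescent libraries. No 2 files held the same values, and the libraries of any pair shared at most 406 circles, so each was counted as 1 sample. The pair with the most shared circles, PDL 23 and 54, crosses the groups and also holds the 2 libraries that list the most circles. Over the 110 circles that passed the filter its Spearman rho was 0.546. The proliferating pair had 0.152 and the senescent pair 0.336, so by this measure PDL 23 was closer to a senescent library than to PDL 20. PDL 20 had a read in only 72 of the 110 circles, and its missing circles can lower its rho with any library. Whether some libraries are separate preparations of 1 RNA was not tested.

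**Figure D3:**
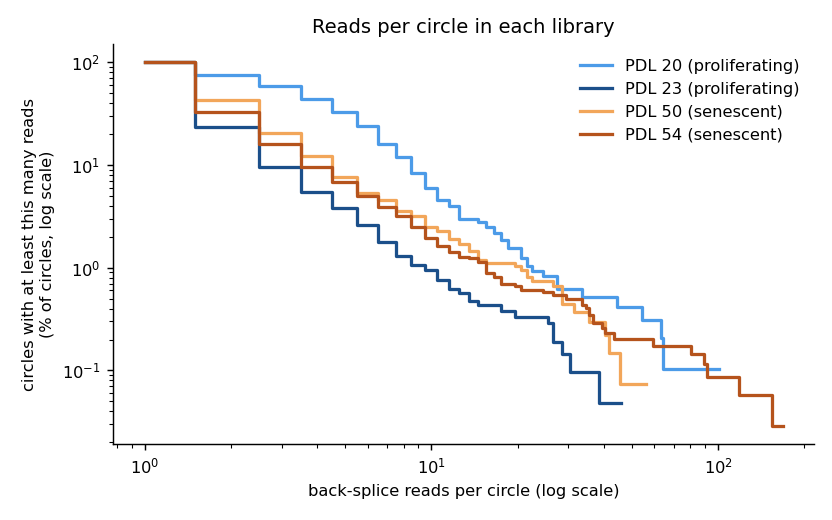
Percent of the circles of each library (log scale) that had at least the number of back-splice reads on the horizontal axis (log scale), 1 line per library. The library at PDL 20 lies above the others at low read numbers, with 25.5% of its circles on a single read against 76.7% at PDL 23.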

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

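Of the tests below, the distance to the 3′ end was chosen after the result was seen and the relation to intron length before. The position of intronic entries within their introns, which no comparison above used, stood out in every library. All intronic entries started at the 5′ end of their intron, and 98.6% at PDL 20, 97.6% at PDL 23, 97.1% at PDL 50 and 96.3% at PDL 54 ended more than 100 nt before its 3′ end. The program that called the circles is not known here, so the shared start may be its rule rather than a property of the RNA. Circles of spliced-out lariats, which close at a branch point usually close to the 3′ end, would end near it. Pooled over the libraries, 3.13% of 4119 distinct entries ended within 100 nt. This is the same observation as above and no separate test, and it argues against lariats for these entries as a set. A candidate explanation is a join within 1 library fragment: over 3032 entries in introns longer than 1000 nt, span and intron length were unrelated (Spearman rho 0.0345 across entries, which are not independent replicates), with a median span of 215 nt over all entries. That median hides spans longer than 350 bp, the upper limit of fragment selection. THBS1 intron 7, which held the most distinct ends (129), had a median span of 442 nt, and THBS1 intron 6 had 532 nt. Other introns with many ends had shorter medians, such as 231 nt in BIRC5 intron 2. RAB7A had far longer spans, with 48 distinct ends in a 9581 nt intron and a median span of 8514 nt. A join within 1 selected fragment thus remains a candidate only for entries within that limit. No biological explanation tied to the groups was tested.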

How the results depend on the processing

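The settings with exonic circles only, and the unfiltered list tests limited to exonic circles, to 3 libraries or with an estimated correlation, and the matrix list without THBS1, were chosen after seeing the data. Under every alternative run, 0 circles and 0 host genes higher in senescent cells passed; the cause of the changes below was not tested. Host genes lower in senescent cells numbered 0 to 8 when single libraries were left out, 8 of them without PDL 23 and 0 under the others. The library at PDL 20 is then the lone proliferating one. circPVT1 passed under none of the settings run and had no value without PDL 23, which holds its only read. The number of host gene lists called was 1 with no filter, 1 with no filter and no library at PDL 20, and 1 with no filter and exonic circles only, the cell division list each time at the preset correlation, against 0 otherwise. These calls at the preset correlation do not measure the spread between libraries. Without PDL 20 the spread of each gene comes from the senescent pair. The log2 ratio of distinct circles at equal depth ran from -0.31 without PDL 20 to 0.85 without PDL 23. The difference in mean log2 length turned to -0.18 for circles that passed the filter and to -0.087 for exonic circles, and the 50 most abundant circles took 4.32 percentage points more in senescent libraries. Leaving out single libraries turned the log2 fold change of abundant circles, with ranges of -0.0075 to 1.54 for BPTF, -0.95 to 0.63 for HIPK2, -2.01 to 7.95 for LPAR1, -0.49 to 0.27 for SPECC1, -0.55 to 1.93 for the shorter TJP1 circle and -0.063 to 8.18 for the longer one. Among host genes the ranges were -0.52 to 1.43 for ATM, -1.22 to 2.89 for LTBP1, -1.33 to 0.78 for PTBP3 and -6.56 to 1.96 for RBM39. With no filter HIPK2 stood at 0.098, SPECC1 at 0.10 and LTBP1 at 0.15, with a filter of 1.5 SPECC1 stood at 0.038, with a filter of 6 LPAR1 stood at -0.15, and with PDL as covariate LTBP1 stood at 0.094. List directions turned too, at unadjusted camera p of 0.804 (extracellular matrix) and 0.573 (TGF-beta) with detection in all 4 libraries, 0.920 (extracellular matrix) with exonic circles, 0.718 (chromatin) unfiltered without PDL 20, 0.817 for the latter with an estimated correlation, and 0.726 (well-described hosts) unfiltered with exonic circles. Leaving out single libraries gave p of 0.0845 to 0.881 for chromatin, 0.147 to 0.961 for extracellular matrix and 0.296 to 0.821 for TGF-beta. Of 33 circles 27, and of 27 host genes 23, never turned. For circles this was largely fixed by the choice, so it does not measure robustness. The 12 circles per direction were named because their groups did not overlap, and leaving out a library can then hardly turn the sign. The circles that turned were all among the 10 most abundant. The spread between libraries limits the calls, since in simulation at the same 3114 to 7475 reads per library a dispersion of 0.1 let 98.5% of 16-fold circle changes be recovered, against 4% at the observed dispersion. Other depths were not simulated, and circPVT1, with 1 read, lies under the floor.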

Other observations

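Of the tests in this part, the circles missing at PDL 20, the level of the second proliferating library and the other splits of the libraries were chosen only after the result was seen.

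THBS1 entries were concentrated in intron 7 (chromosome 15, 39877765 to 39879547, 1783 nt), where 129 distinct ends were listed between 39877911 and 39878657. They held 149 and 157 reads in proliferating and 483 and 281 in senescent libraries, and relative to library totals PDL 50 alone stood apart. BIRC5 had a similar layout, where 19 distinct ends in intron 2 (chromosome 17, 76210871 to 76212046) held 44 and 8 reads in proliferating and 0 and 3 in senescent libraries. The mitotic genes CDC20 (12 and 11 against 0 and 2 reads) and HJURP (12 and 5 against 0 and 2), which were not on the cell division list and were chosen after their values were seen, had the same order as BIRC5.

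The smaller share of cell division circles in the senescent libraries is a hypothesis worth following up. With each circle counted once, the shares were 1.45% and 0.908% in proliferating and 0.147% and 0.260% in senescent libraries, and the lowest proliferating value lay 0.648 percentage points above the highest senescent one, with counting intervals that did not overlap. This order is the one the senescent state named in the labels would give, but it comes from the same circles and libraries in which it was first seen. An exact permutation p cannot fall below 0.333 here. The read shares of the well-described hosts, RNA-binding and actin lists did not overlap between the groups either. Repeated reads of few molecules at PDL 20 could add to the difference: at PDL 23 the share of distinct circles was 3.50 times that of the higher senescent library, with an interval of 1.51 to 8.77 that includes the bound of 2 set for excluding this, so the counts are too few to decide. Exonic and intronic entries had the same order, with 1.32% and 0.629% against 0% and 0.0985% of exonic reads and 1.28% and 0.925% against 0.136% and 0.167% of intronic reads.

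The library at PDL 20 had few circles resting on a single read. Deeper sequencing is argued against, since at equal depth its share stayed 26.9 percentage points below the next library. The proliferating state is argued against as well, though by 1 library alone. At equal depth PDL 23 stood at 77.3%, 20.4 percentage points above the lower senescent library, PDL 50. The other senescent library, PDL 54, stood close to PDL 23 at 76.2%. Fewer starting molecules, each read several times after amplification, may account for the few single-read circles at PDL 20 and would leave out circles at random. Of 83 circles listed in all 3 other libraries, with at least 3 reads expected at its depth, 42 (50.6%) were missing at PDL 20. This was 31.5 percentage points above the highest share another library lacked of its own such set (19.1% at PDL 50). The sets are unlike, since those of the other libraries hold only circles listed at PDL 20, which has the fewest circles. The comparison thus partly restates the low number of circles, and cannot tell few molecules from a sample that truly differs.

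The 4 libraries can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 8 circles at an unadjusted p under 0.05 and was the 1 split with as many, the highest other split giving 2. This circle count rose when PDL 23 was left out and fell when PDL 20, 50 or 54 was, in fits with 1 library in a group. It therefore depends on single libraries and does not by itself show a group difference. For host genes the real split gave 18 and the highest other split 10.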
